A study of Drosophila melanogaster with 2 samples.

How the data were processed

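Chromatin immunoprecipitation sequencing (ChIP-seq) of HLH3B was carried out on whole Drosophila melanogaster embryos aged 8 to 24 hours that carried an HLH3B-eGFP transgene, per the labels. The fusion protein was precipitated with an antibody against GFP, and chromatin was fragmented by sonication to a size range of 200 to 800 bp. The series held 1 group of 2 biological replicates and no second condition. The control experiment was not analysed here.

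Only the authors' peak lists were used, with coordinates on assembly dm6 per the labels. Each list gave a position, a score, a signal value, a q-value and a summit for every peak. The score was deposited as a whole number that equalled a rescaled irreproducible discovery rate (IDR), a measure of how well peak ranks repeat. The signal value of each peak was the authors' own, on a scale that is not given in the sources used here, and it served only to rank and describe peaks within a list. The −log10 IDR was also the authors' value, and it served to tell candidate peaks that passed the threshold from those that missed it. The deposited q-values were not used here. The peak caller, the aligner and their versions are not given in the sources used here. The deposited text notes state that thresholded lists were made with 1 further file that the ranked candidate lists did not use. The depth of each library is unknown, because the lists hold no read counts.

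The authors deposited a thresholded list and a ranked candidate list for each replicate and for each of 2 series-level sets. The main set was the conservative IDR-thresholded set, whose peaks are a subset of a candidate list that compared the replicates. All peaks of the main set had an IDR of 0.01 or lower, and 1 interval that occurred with 2 summits was kept as 2 sites. Peaks were placed on the arms 2L, 2R, 3L, 3R, 4 and X. The files hold no chromosome lengths, but every peak on these arms fitted inside the arms of the Release 6 reference sequence. Genes came from Ensembl release 115 (build BDGP6.54) without transposable elements, which gave 18164 genes.

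Replicate peaks were counted as shared when they overlapped by at least 1 bp, against 1000 shifts of the replicate 2 peaks along the same arms (permutation test, one-sided). Promoter summits lay within 1000 bp of an annotated transcription start, against 1000 sets of random positions on the same arms (permutation test, two-sided). Motifs were searched on both strands within 50 bp of each summit and in a window of equal width 300 bp away on a random side (exact two-sided sign test). Benjamini-Hochberg adjustment was applied over the 10 E-box classes, over the 3 other motifs and over 2080 hexamers. Composite CTG and GATA elements were counted within 100 bp of summits at spacings of 0 to 20 bp (exact Poisson test conditional on the total, one-sided). A gene counted as bound with a summit in its body or up to 2000 bp upstream. For 22 gene lists the number of bound members was compared with 10000 random lists matched on decile of gene length (permutation test, two-sided, Benjamini-Hochberg over lists). Of 488 list entries all 488 were matched, 11 of them through a current symbol. Shares carry Wilson 95% intervals, which cover counting error only.

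The genes named were set by a rule written before the data were examined, as were the lists and tests. HLH3B came before the others. The 15 genes of the strongest main-set sites followed, each site given to the nearest start. For each list the rule took up to 4 bound members with the highest signal where the list passed its test, and up to 2 otherwise. Alternatives covered the other series-level set, each replicate alone, the upper part of the main set by signal, other windows, other overlaps, other backgrounds and other matching of genes. A background of candidate peaks used up to 5 candidates per site that missed the IDR threshold and overlapped neither series-level set. A further background of 100 dinucleotide-preserving shuffles per window was added after the summits were seen to be AT-rich.

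The tests were tried on simulated data. For the hexamer test at summits, CAGATG placed in 10% of 4000 random windows ranked 1 among 2080 hexamers, and 0 hexamers passed without it. Both simulated window sets were drawn at random from the same arms. The difference in base composition between summits and the windows beside them was therefore not simulated. For the gene-list test, 50 of 50 lists with a 3-fold excess passed, and 0 of 150 unchanged lists did, among 200 lists tested together. Smaller excesses and deficits were not simulated, so the power to find them is not known. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 were used.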

Results

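The binding of HLH3B, a basic helix-loop-helix (bHLH) protein of the Tal1 type, was mapped in whole fly embryos aged 8 to 24 hours. The embryos carried HLH3B fused to eGFP, and ChIP-seq was done with an antibody against GFP. The data were peak lists from 2 biological replicates of 1 group, so the design gives a map of binding and a comparison of replicates. Peak signal values are the authors', and depth is unknown.

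The main set held 3846 binding sites, with a median width of 336 bp and a median signal of 139. The X chromosome carried 33.3 sites per Mb (exact Poisson 95% interval 31.1 to 35.8), and arm 3R carried 26.6 (24.8 to 28.4). Arms 2L, 2R and 3L lay between them at 29.3, 27.2 and 29.5 sites per Mb. The small chromosome 4 carried 3 sites, or 2.23 per Mb (0.459 to 6.50). The other series-level set held 5814 sites and contained 3693 of the main set's sites unchanged.

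HLH3B itself carried no site of the main set. The gene (FBgn0011276) lies on X from 2680199 to 2681723 on the minus strand (dm6). Measured from the start of HLH3B, the nearest sites lay 34.1 kb to the left, with a signal of 105, and 22.2 kb to the right. The site to the right, at the start of Ugalt, had the highest signal of the whole set.

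Most of the strongest sites lay next to the starts of genes. Ugalt, a UDP-galactose transporter, had the strongest site (X 2703700 to 2704059, signal 2837), with its summit 28 bp upstream of the start. mRpL41, a mitochondrial ribosomal protein (site on 2R, 15217590 to 15217917), had a signal of 2093 with its summit 131 bp upstream. Of the 15 strongest named genes, 10 had the summit within 150 bp of a start, 9 of them upstream. All 15 sites ranked 23 or better in replicate 1 and 21 or better in replicate 2.

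CG11050 carried the next strongest site after Ugalt (2L 6612529 to 6612889, signal 2555), which lay in an intron 1019 bp from a start. CG14100 (3L 19590458 to 19590778, signal 2278) and CG7601 (3R 29736667 to 29736998, signal 2019) had intergenic summits 90 and 97 bp upstream. The Polycomb-group gene ph-p had an intronic summit 499 bp upstream of its nearest start (X 2137183 to 2137527, signal 1959). The site given to CG13323 (2R 13035195 to 13035488, signal 1837) lay 11923 bp from that gene's nearest start. CG18549, the arginine methyltransferase gene Art3 and CenG1A had summits 129, 127 and 100 bp upstream, with signals of 1798, 1745 and 1735. The site at px was intronic and 204 bp upstream of a start, with a signal of 1733. Tcs5 and CG5611 had summits 99 and 111 bp upstream, with signals of 1666 and 1563. PNPase, a polynucleotide phosphorylase, had its summit in the 5' UTR, 81 bp downstream of its nearest annotated start (signal 1619). The non-coding gene lncRNA:CR45643 had a site 903 bp upstream (signal 1552).

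Most replicate 1 sites were found again in replicate 2. The replicates held 3992 and 3546 peaks (mean 3769 ± 315, SD, n = 2). Of 3992 replicate 1 peaks, 2479 overlapped a replicate 2 peak, or 62.1% (Wilson 95% interval 60.6 to 63.6%). Shifted replicate 2 peaks overlapped 1.43% on average (permutation test, one-sided, p = 0.001, the smallest the shifts can give). Of the main-set sites, 3602 (93.7%) had a candidate summit within 100 bp in both replicates. Spearman's rho of the replicate signals across these sites was 0.767, where sites are not independent replicates. The main set was chosen for ranks that repeat between replicates, so both values describe the set and do not test repeatability.

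**Figure D1:**
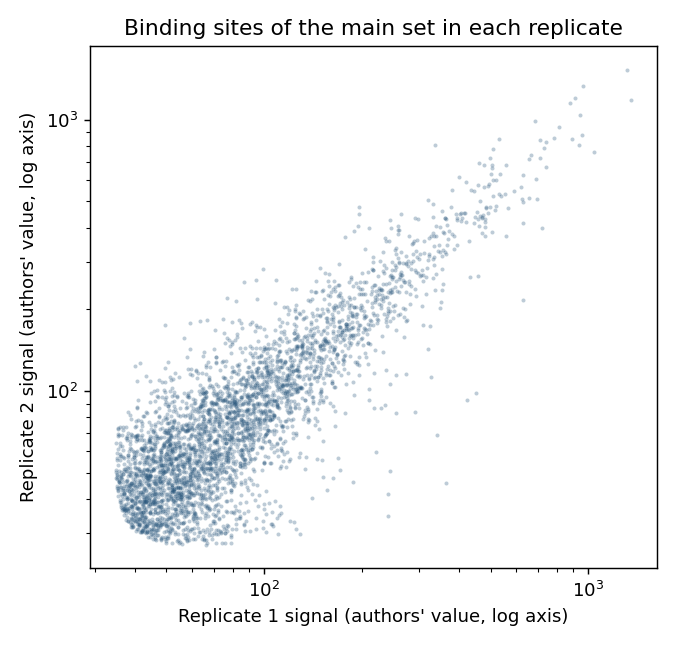
Signal of each main-set site in replicate 1 (x axis) and replicate 2 (y axis), both the authors' values on log axes, 1 point per site. The 3602 sites found in both replicates rise together, with a Spearman's rho of 0.767.

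Sites of the main set gathered at promoters, just upstream of transcription starts. Neither the control nor another tagged protein was analysed here. A general pull-down at promoters therefore cannot be told apart from binding proper to HLH3B. Of 3846 summits, 2063 lay within 1000 bp of a start, or 53.6% (Wilson 95% interval 52.1 to 55.2%), against 23.6% of random positions on the same arms. The log2 ratio was 1.18 (permutation test, two-sided, p = 0.002, the smallest possible). Promoter summits lay at a median of -116 bp from the start, with quartiles of -246 and -8.5 bp. They were upstream of the start in 1566 cases, or 75.9% (74.0 to 77.7%), and belonged to 1813 genes. Against candidate peaks that missed the threshold, of which 29.2% were promoter summits, the log2 ratio was 0.88 (Fisher's exact test, two-sided, p = 1.95e-179).

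Coding sequence was almost free of summits. Coding exons held 27 summits, or 0.702%, against 17.1% of random positions, and 3' UTRs held 1.46% against 4.98%. The 5' UTRs held 6.11% against 3.06%. Introns held 50.7% against 42.7%, and intergenic sequence held 38.2% against 30.4%. Non-coding exons held 2.78% against 1.76%. Each of these 6 classes differed from random positions (permutation test, two-sided, adjusted p = 0.002).

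**Figure D2:**
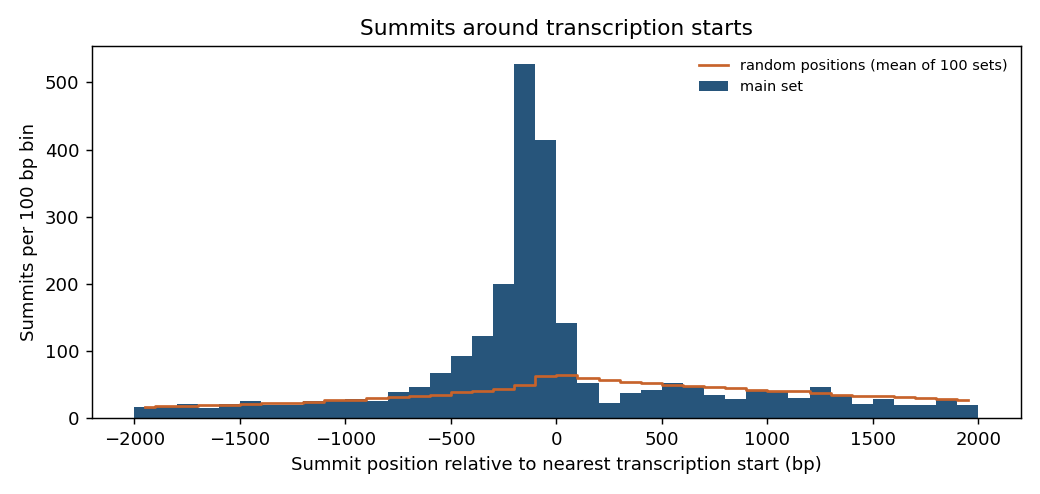
Number of main-set summits per 100 bp bin (bars) by position relative to the nearest transcription start in bp, with the mean of 100 sets of random positions (line). The bars peak just upstream of the start, where the median promoter summit lies at -116 bp.

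The E-box CAGATG, the textbook site of Tal1-type proteins, was less frequent at summits than beside them. It occurred at 108 of 3846 summits, or 2.81% (Wilson 95% interval 2.33 to 3.38%), against 4.13% of windows 300 bp away. The log2 ratio was -0.56 (exact two-sided sign test, p = 0.00176, adjusted p = 0.00252). Against dinucleotide shuffles of the same summit windows, chosen after the data were seen, the log2 ratio was -0.0025 (permutation test, two-sided, p = 0.951).

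Of the 10 E-box classes, 7 were less frequent at summits at an adjusted p under 0.05. The palindromes CACGTG and CAGCTG had log2 ratios of -1.42 and -0.74, with adjusted p-values of 0.000108 and 3.52e-05 (exact sign test). CACCTG, CACATG, CAACTG and CAAGTG had log2 ratios of -0.89, -0.77, -0.66 and -0.56. Against the shuffles the direction turned for CAGCTG, CAAGTG and CAACTG, with log2 ratios of 1.15, 0.49 and 0.25 (permutation tests, two-sided, p = 0.0198, 0.0198 and 0.0396). The windows 300 bp away exceeded their own shuffles too, at 1.07, 0.60 and 0.53 (permutation tests, p = 0.0198 for each), so the excess was not particular to summits. CACATG and CACGTG stayed lower, at -0.33 and -0.72 (permutation tests, p = 0.0198 and 0.0396), and CACCTG did not differ detectably, at 0.17 (permutation test, p = 0.297). CATATG was at 3.77% of summits and 3.09% of windows beside them, and did not pass (exact sign test, adjusted p = 0.146). CAAATG and CAATTG did not pass either, with log2 ratios of -0.13 and -0.18.

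The GATA motif WGATAR, bound by GATA factors such as those in vertebrate Tal1 complexes, was more frequent at summits. It occurred at 863 summits, or 22.4% (Wilson 95% interval 21.1 to 23.8%), against 15.1% of windows beside them. The log2 ratio was 0.57 (exact two-sided sign test, p = 7.96e-17). Against dinucleotide shuffles of the same windows, chosen after the data were seen, the direction turned, with a log2 ratio of -0.23 (permutation test, two-sided, p = 0.0198, the smallest possible). The windows 300 bp away did not differ detectably from their own shuffles, at -0.035 (permutation test, two-sided, p = 0.515). GAGAG, the motif of the GAGA factor Trl, was at 8.48% of summits against 16.3% beside them, and its direction also turned against the shuffles, with a log2 ratio of 0.41 (permutation test, p = 0.0198), close to the 0.37 of the windows beside them against their own shuffles. CAGGTA, the motif of the early activator Zelda, was at 1.51% against 2.21% (exact sign test, adjusted p = 0.0282), and stayed lower against the shuffles, at -0.68 (permutation test, p = 0.0198). In the windows beside summits CAGGTA did not differ detectably from its shuffles, at -0.027 (permutation test, p = 0.970).

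CTG and GATA elements showed no excess at the spacing of the textbook Tal1 composite site. Spacings of 7 to 9 bp held 203 elements, against 202.3 expected from the other spacings. The ratio was 1.00 (exact Poisson test, one-sided, p = 0.494).

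Hexamers made of A and T set the summits apart. Of 2080 hexamers, 501 were more frequent at summits and 1014 less frequent (exact sign test, adjusted p under 0.05). TTAAAA had the smallest p, at 35.4% of summits against 13.5% beside them (log2 ratio 1.39). Next by p came AAATAT, AATATA and ATATTA, with log2 ratios of 1.31, 1.63 and 1.86. All 36 hexamers of A and T alone were more frequent. Of the 36 made of G and C alone, 34 were less frequent, among them CCGCCG at 0.936% against 5.41%. The mean G+C content was 32.6% ± 9.49 (SD across 3846 windows) at summits and 44.3% ± 9.81 beside them.

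**Figure D3:**
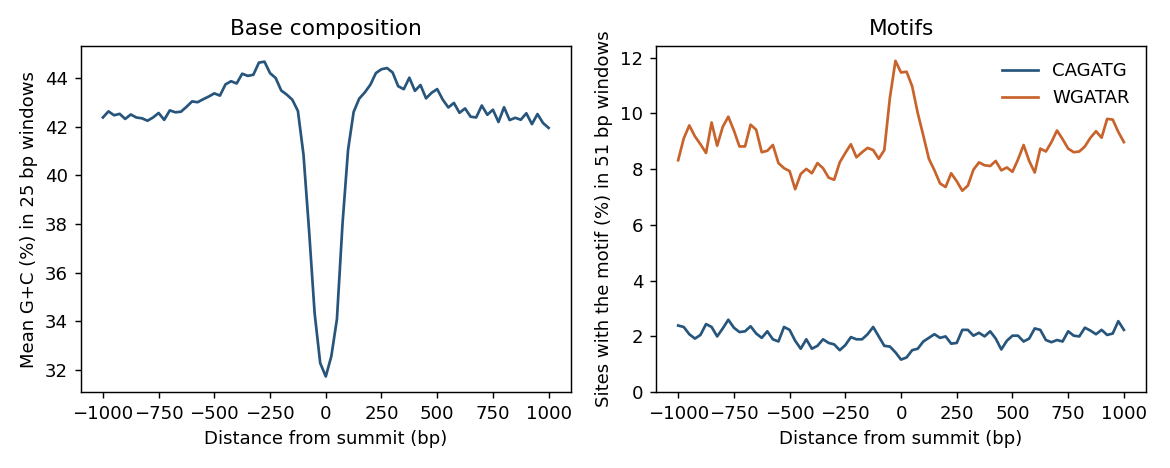
Mean G+C content in percent in 25 bp windows (left) and percent of sites with CAGATG or WGATAR within 25 bp of each position (right) by distance from the summit in bp, over 3846 sites. These windows are narrower than the 50 bp to each side used in the tests. G+C falls to 31.7% at the summit, where WGATAR rises to 11.5% and CAGATG falls to 1.17% of sites.

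Binding by gene group set ribosomal protein genes apart from the other lists. Of 18164 genes, 3686 (20.3%) were bound, and 2 of 22 lists differed from matched random lists. Of 40 listed cytosolic ribosomal protein genes, 25 were bound (62.5%, Wilson 95% interval 47.0 to 75.8%), against 6.74 expected (permutation test, two-sided, adjusted p = 0.0044). The list is not the whole family. RpS27 is not on it and had a site with a signal of 447, with its summit 33 bp upstream, and was chosen here after its value was seen. In 24 of the 25 bound members of the list the strongest summit lay within 1000 bp of a start. RpL7 had a signal of 435 with its summit in the 5' UTR, 24 bp inside the gene. RpL32, RpL14 and RpS20 had signals of 380, 358 and 222 with summits 116, 44 and 196 bp upstream. RpL5 and RpL11 were among the 15 members without a site, and were chosen here after their values were seen.

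Genes for dopamine and neuropeptide signalling were bound less often than matched genes. Of 25 members 1 was bound, against 7.48 expected (permutation test, two-sided, adjusted p = 0.0286). The bound member was Tbh, the enzyme that makes octopamine, with a signal of 91.1 and a summit 415 bp upstream. The Tbh site had no candidate summit within 100 bp in replicate 1 and ranked 3425 in replicate 2. The call was lost in 5 of 9 alternatives, with an adjusted p of 0.339 when sites were given to the nearest start and 0.106 without replicate 2 (permutation tests). The ratio of bound to expected genes stayed below 1 there, at 0.230 and 0.261.

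Other neuronal lists had low counts that did not pass the adjustment. No GABAergic gene of 10 was bound against 3.77 expected, and 2 of 18 cholinergic and glutamatergic genes were, against 7.16 (permutation tests, two-sided, adjusted p = 0.0902 for each). The latter were ChAT, the enzyme that makes acetylcholine (signal 277), and the muscarinic receptor gene mAChR-A (signal 128). Of 19 pan-neuronal genes 5 were bound against 8.63 expected, including the RNA-binding protein genes elav, with a signal of 637, and fne, with 222. Neuroblast and temporal factors had 4 of 19 bound against 6.30, including brat (signal 768) and grh (signal 273). Neuronal identity factors had 6 of 27 bound against 10.7, including otp (signal 518) and zfh1 (signal 399). The otp site lay in a coding exon 12990 bp from the nearest otp start, and the start of Cib2 was nearer, at 4664 bp.

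Partners of the Tal1-type complex were bound about as often as matched genes, at 6 of 15 against 5.84 expected (permutation test, two-sided, adjusted p = 1). The Friend-of-GATA gene ush had an intronic site with a signal of 349, and its gene body also held a candidate past the IDR threshold that the main set leaves out, with a signal of 2484. In the same list, the LIM-only gene Bx had an intronic site with a signal of 247. Blood cell genes had 8 of 26 bound against 9.32, led by zfh1 and ush. The bHLH family had 10 of 33 bound against 8.73, led by sim (signal 229) and crp (signal 223). The sim site had a signal of 172 in replicate 1 and 51.4 in replicate 2, and the crp site had 102 and 118. The Notch pathway had 10 of 22 bound against 6.19, including the corepressor gene gro (signal 498) and the receptor gene N (signal 394), with an adjusted p of 0.274 (permutation test, two-sided).

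Glial genes had 10 of 25 bound against 8.91, including moody (signal 768) and the glutamine synthetase gene Gs2 (signal 280). Septate junction genes had 9 of 19 bound against 5.78, including Tsf2 (signal 369) and bark (signal 343). Muscle genes had 12 of 31 bound against 11.5, including the muscle regulator Mef2 (signal 754) and kirre (signal 374). The Mef2 site lay 1085 bp upstream of Mef2, but the start of Pal1 was nearer, at 135 bp. Heart genes had 4 of 17 bound against 5.43, including tin (signal 608) and zfh1. Tracheal genes had 7 of 16 bound against 6.61, including rib (signal 303) and sty (signal 269). Ecdysone response genes had 10 of 17 bound against 7.29, including the nuclear receptor genes Hr3 (signal 987) and Hr4 (signal 651). Ecdysteroid synthesis genes had 2 of 19 bound against 5.46, which were ken (signal 288) and ftz-f1 (signal 188).

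Epidermal and cuticle genes had 3 of 22 bound against 7.49, including grh and ovo (signal 188). Midgut genes had 3 of 16 bound against 4.20, including bin (signal 160) and the GATA factor gene grn (signal 103). Fat body genes had 5 of 14 bound against 4.32, including the lipase gene bmm (signal 278) and Mtp (signal 135). Odorant and gustatory receptor genes had 4 of 38 bound against 6.78, including Or88a (signal 189) and Gr32a (signal 126).

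**Figure D4:**
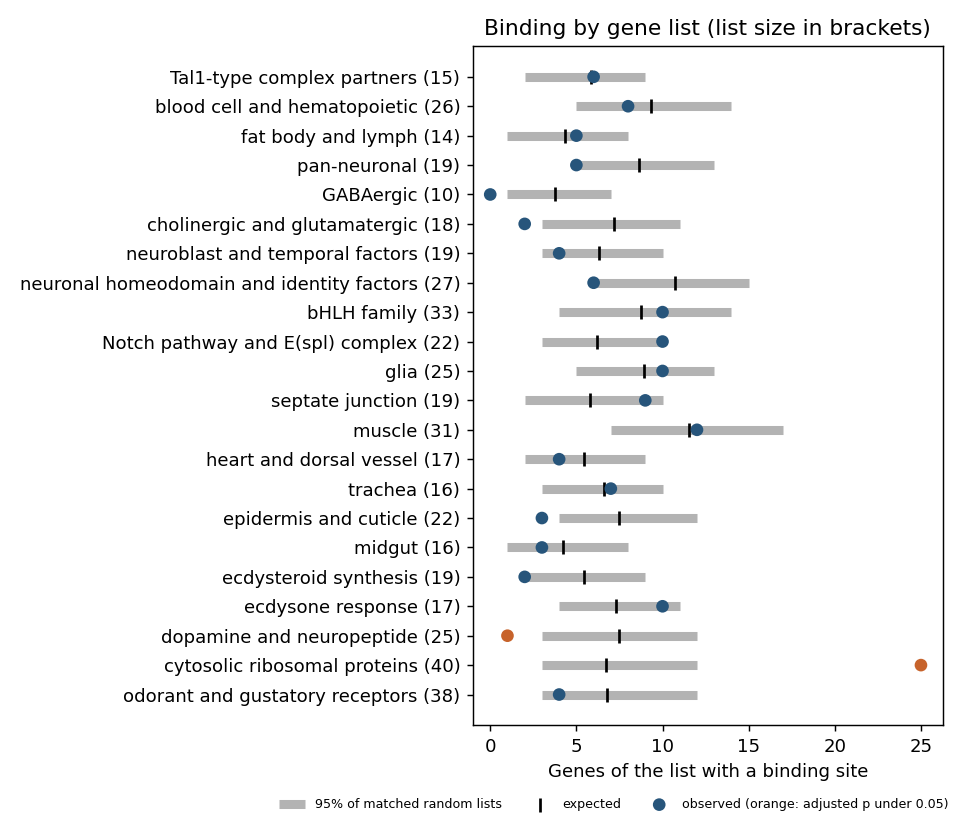
Number of genes with a binding site in each of 22 lists (points), the number expected (black marks) and the 95% range of length-matched random lists (grey bars). Cytosolic ribosomal proteins stand above their range with 25 genes, and dopamine and neuropeptide genes stand below with 1.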

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

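The tests of ribosomal protein and tRNA genes, of base composition and of the HLH3B neighbourhood were set after the patterns were seen but before their own results were known. The reading of the tRNA test as open was set after its result was seen, because the written expectation gave no bound for an interval that spans the random share.

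A signal appeared in candidates that the main set leaves out. Of 3917 candidate peaks past the IDR threshold, 71 are absent from the main set, 43 of them on 3R and 18 on 2L. None of the 71 overlapped a thresholded set, while 68 lay at peaks past the threshold among the candidates of the other series-level set. Among the candidates of replicates 1 and 2, 60 and 54 of the 71 lay at such peaks. The thresholded lists were made with 1 further file that the candidate lists did not use. Whether that file removed these peaks was not tested, so they are not read as binding that was missed. Of the 100 strongest candidates, 7 were among the 71. The strongest lay near cbt and inside the gene body of ush (2L 480925 to 481264, signal 2484) and would rank 3 by signal, and another lay near Lk6 (3R 11760893 to 11761198, signal 1605). Among listed genes, crp also held a left-out candidate (signal 228), as did Ssdp and Syx1A (signals 124.7 and 96.4), which had no site in the main set. These genes were named after their values were seen.

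Signal also appeared outside the 6 arms used. The replicate 2 set held 38 peaks on other sequences of the assembly, against 0 in the replicate 1 set.

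Listed ribosomal protein genes carried binding more often than length-matched genes, 25 of 40 against 6.74 expected. Crowded gene neighbourhoods were argued against, since the ratio stayed at 2.93 with random lists matched on nearby starts. A general pull-down at highly transcribed loci may still contribute. Of 295 tRNA genes, 7 had a summit within 250 bp, 1.49 times the number at random positions (permutation test, one-sided, p = 0.181). The Wilson 95% interval of 1.15 to 4.82% spans the random share of 1.59%, so this explanation and binding proper to these genes cannot be told apart here. No biological explanation was tested.

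The scarcity of CAGATG and the excess of WGATAR at summits, against windows 300 bp away, are consistent with the base composition of the AT-rich summits. CAGATG occurred 0.998 times as often as in dinucleotide shuffles of the same windows, and WGATAR 0.850 times as often. In the flanking windows these values were 1.01 and 0.976. Composition alone leaves the deficit of WGATAR at summits open. It also leaves other E-boxes open on either side, with CACATG and CACGTG at 0.795 and 0.608 times their shuffles (0.911 and 0.773 in the flanking windows) and CAGCTG, CAAGTG, CATATG, CAACTG and CAAATG at 2.22, 1.40, 1.32, 1.19 and 1.17 times (2.10, 1.51, 1.34, 1.44 and 1.18 in the flanking windows). No biological explanation was tested.

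The strongest site of the main set lay 22.2 kb from the start of HLH3B, at Ugalt. If extra copies of the locus in the transgene raised the signal, other candidates within 25 kb would be high too. Their median signal of 24.2 stood at the 78.1 percentile of 929 random windows, above the random median of 21.5 and below the 95th percentile of 28.0. This argues only against copies that raised the signal across the whole window. The HLH3B gene body itself held no candidate peak. How much of the window the transgene holds is unknown here, so copies of a part of it stay open. The scale of the signal is not given, so whether extra copies would raise it is also unknown. Of 13945 protein-coding genes, 0.911% had 1 of the 10 strongest sites within 25 kb, but 10 such windows cover only 0.373% of the arms, which fixes a low share wherever the sites lie. The test is void, and a chance position stays open.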

How the results depend on the processing

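The shuffled background, the match on nearby starts, the count from replicate 2, sites that overlap no other site, the repeats of the hexamer test, and those of the spacing test in each replicate alone and in the upper part by signal were chosen after seeing the data. The site count was 5814 in the other series-level set, 1923 in the upper part by signal, and 3546 to 3992 with 1 replicate alone. The shared share of 62.1% became 53.2% with reciprocal overlap, 59.2% with summits within 100 bp, 70.0% in the upper part by signal, and 69.4% counted from replicate 2. The promoter excess kept its direction and call in all 8 alternatives, with log2 ratios of 0.81 to 1.66. CAGATG kept its direction and call in 7 of 8 alternatives and lost the call against shuffles (log2 ratio -0.0025). WGATAR kept both in 7 of 8 and reversed against shuffles (-0.23). Shuffles keep the windows' own composition, and CAGATG occurred 0.998 times as often as in them. The cause of the reversal of WGATAR was not tested. Spacing did not pass in any of 5 alternatives. Higher hexamers numbered 405 to 515 in 4 alternatives. Lists that passed fell from 2 to 1 in the other set, in the upper part by signal, with the nearest start and with the match on nearby starts, and were 1 to 2 with 1 replicate alone. The cause was not tested. Cytosolic ribosomal proteins passed in all 9 alternatives. No paired analysis was possible because there is 1 group. Depth is unknown, so its limits could not be given.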

Other observations

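The tests of gene families and of promoter motifs here were chosen after the data were seen; the test of divergent starts was not run until its expectation was written.

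Of 12 families told apart by symbol, 4 differed in binding from matched genes. Of 73 mitochondrial ribosomal protein genes 19 were bound against 9.55 expected (permutation test, two-sided, adjusted p = 0.0138 over 12 families). Ionotropic receptor genes had 1 of 60 bound against 12.5 (permutation test, adjusted p = 0.0024). Cuticle protein genes had 3 of 70 bound against 11.4, and cytochrome P450 genes had 6 of 85 against 17.3 (permutation tests, adjusted p = 0.0136 and 0.012). Proteasome subunit genes had 7 of 48 bound against 7.77, and translation initiation factor genes had 13 of 44 against 9.94, and neither passed. Respiratory complex I genes had 11 of 34 bound against 5.67 and did not pass the adjustment (permutation test, adjusted p = 0.0797). The others that did not pass were aminoacyl-tRNA synthetases with 7 of 17 bound against 3.92, odorant-binding proteins with 2 of 51 against 6.42, Jonah proteases with 0 of 16 against 2.02, Osiris genes with 1 of 25 against 4.92 and Twdl genes with 1 of 23 against 3.24.

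The core of the CTCF motif, AGRKGGCGC, occurred at 65 summits against 13 windows beside them (exact two-sided sign test, adjusted p = 5.42e-09), and at 2.69 shuffled windows on average. TATCGATA, the element shared by DREF and BEAF-32, occurred at 38 summits against 19 windows beside them (exact sign test, adjusted p = 0.0245), but exceeded its shuffles about as much in both, 6.06 times at summits and 5.69 times beside them. GGTCACACT, the element of M1BP, occurred at 13 against 5 and did not pass (exact sign test, adjusted p = 0.0963). It exceeded its shuffles 12.4 times at summits (permutation test, two-sided, p = 0.0198) and 2.91 times beside them (permutation test, p = 0.119).

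Stronger sites were more AT-rich and more often at promoters. In the top quartile by signal, G+C at the summit was 30.0% and 65.4% of summits were promoter summits. In the lowest quartile these values were 35.9% and 47.3%. Candidates that missed the threshold had 47.5% G+C at the summit.

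Promoter summits lay between divergent starts more often than the random promoter positions drawn here. Of 2063 promoter summits, 684 (33.2%, Wilson 95% interval 31.2 to 35.2%) lay within 1000 bp of starts that point away from each other on both sides. Random promoters with the same offsets gave 21.2% on average and 23.3% at most over 100 sets (permutation test, one-sided, p = 0.0099, the smallest possible). Observed offsets were to the nearest start, but a random position was not required to keep its drawn start as the nearest. All annotated starts were drawn with equal weight. The random share may therefore be off, and whether promoter position alone gives the observed share stays open. A candidate explanation is that divergent promoters hold wider open regions, which was not tested.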
